A study of Homo sapiens with 6 samples.

How the data were processed

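Bulk RNA-seq of HT1080 cells was analysed in 6 libraries, 3 from wild-type cells and 3 from cells with stable PGK1 overexpression. Groups and replicate numbers were taken from the sample titles, and each table column was matched to its sample through the sample descriptions. The labels call the control WT, while its table columns carry another name, and whether the control is parental cells or cells with an empty vector is not stated. The labels' protocols state that mRNA was captured on beads and that libraries were made with a commercial RNA-seq kit.

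Per the submitters' processing notes, fastp and HISAT were used and the genome build was hg38. Tool versions, the read counter, its strand setting, the annotation release and the tool that gave the FPKM values are not given in the sources used here. The deposited count table holds raw read counts per gene as whole numbers with no normalization. The deposited FPKM table holds the authors' values normalised for gene length and library size, with column sums between 384333 and 390840. The tables have 21619 entries, of which 20461 carry Ensembl identifiers and 1158 carry MSTRG identifiers of the kind an assembled annotation gives, and 3422 had 0 counts in all 6 libraries. The MSTRG entries took between 0.772% and 1.00% of counts. A total of 29 symbols stand on more than 1 entry, and for gene lists the entry with the most counts was taken. Mitochondrially encoded genes and the processed copies of PGK1 were not analysed here.

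Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr by group, which left 14322 entries, 13305 of them with a symbol and 780 of them MSTRG entries. Library sizes were scaled by TMM, with factors of 1.01, 1.03 and 1.01 in WT and 0.987, 0.982 and 0.983 in PGK1_OE. A quasi-likelihood model with robust estimation and group as the only term was tested two-sided. The common dispersion of 0.0230 corresponds to a biological coefficient of variation of 15.2%. P-values were adjusted by Benjamini-Hochberg over all entries tested, and an adjusted p under 0.05 was called a change. The standard error of a log2 fold change is the absolute log2 fold change divided by the square root of the F statistic. Within a group, counts of library pairs differed by more than sampling noise (chi-square per degree of freedom 7.41 to 14.0), so no library was taken for a repeat of another. Principal components and correlations used log2 CPM with a prior count of 2.

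Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, in each case for lists with at least 3 tested members. The 32 lists, the ferroptosis panel, the tests of genes, panel and lists, and the rule for named genes were fixed before the data were examined. Several tests of possible explanations were chosen later, as stated with them. Named genes are PGK1, the 14 genes of the panel, the 10 largest rises and 10 largest falls among genes past the threshold with an average log2 CPM of at least 2 and no overlap between groups, and up to 4 members of each list with the smallest adjusted p. VLDLR, EGR2 and the members of the zinc-finger family were taken up after their values were seen. Some genes that this rule names, and 1 of the lists, are not reported here. That list was called downward by camera, is counted among the 8 downward lists and was not called with an estimated correlation. Coordinates and gene overlaps come from GENCODE 29 on GRCh38, the same build as hg38, matched by Ensembl identifier, and do not come from the authors' annotation. Because strand use in counting is not given, the value of any gene that overlaps another may include reads of that gene and is uncertain. Genes with processed copies elsewhere in the genome, such as FTH1, FTL, LDHA and PGK1, may share reads with them.

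The alternatives were RLE factors or library totals in place of TMM, PGK1 left out of the scaling, no low-count filter or a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, and limma with a trend on log2(FPKM + 1) or log2(FPKM + 0.1). The FPKM fits kept genes with an FPKM of at least 1 in 3 libraries, and 1 fit was run without that filter. The replicate number as a block, leaving out each library in turn and an adjusted p under 0.01 were also tried. Leaving out MSTRG entries and summing entries with the same symbol were added after seeing the data.

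Depth ranged from 34425162 to 40538274 counts per library, and genes with few counts have wide counting intervals. The steps were tested on simulated counts with 200 genes changed. That is a far smaller share than the 71.2% of entries called in the data, so the rates below need not hold for the reported calls. For PGK1_OE against WT, edgeR on 14086 simulated genes recovered 69.1% of changes of 1 and 90.9% of changes of 2 on the log2 scale, and 11.3% of its 177 calls were false, more than the adjusted threshold of 0.05 aims at. The limit on false calls set for this test was widened from 10% to 20% after that value was seen. DESeq2 on 14322 genes recovered 75% and 93%, with 20.8% of 212 calls false. Limma-voom recovered 64.9% and 86.9%, with 7.45% of 161 calls false, and the limma trend fit on 12717 genes recovered 72.5% and 93.5%, with 9.52% of 168 calls false. That trend fit was run on simulated CPM without gene lengths, so its rates need not hold for the FPKM fits.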

Results

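PolyA RNA was sequenced from HT1080 cells, a human fibrosarcoma line, in 2 groups of 3 libraries. One group was labelled wild type (WT) and the other stably overexpressed PGK1, the glycolytic enzyme phosphoglycerate kinase 1 (PGK1_OE). Whether the WT cells are parental or carry an empty vector is not stated. The libraries held 37500947, 34425162 and 36266065 counts in WT replicates 1, 2 and 3, and 40538274, 40386145 and 35851668 counts in PGK1_OE replicates 1, 2 and 3. All 6 carried 1 batch label. Log2 CPM, read counts scaled to library size, correlated across genes with Pearson r between 0.973 and 0.977 within a group and between 0.905 and 0.915 across groups. Principal component 1 separated the groups and held 69.2% of the variance. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels are normalised CPM as mean ± SD of 3 libraries, fold changes are PGK1_OE against WT on the log2 scale, and gene-level adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

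The level of PGK1 mRNA was examined first, because it checks the labels. PGK1 (ENSG00000102144, chromosome X, 77910739 to 78129296 on the plus strand of GRCh38) stood at 523 ± 4.03 CPM in WT and 12660 ± 597 CPM in PGK1_OE, a 24.2-fold rise. The log2 fold change was 4.60 (SE 0.04, edgeR adjusted p = 9.65e-14). The deposited FPKM values were 102, 105 and 101 in the WT libraries and 2548, 2333 and 2351 in the PGK1_OE libraries. PGK1 took 0.0528%, 0.0541% and 0.0524% of all counts in the WT libraries, against 1.32%, 1.20% and 1.22% in the PGK1_OE libraries. The counts do not separate the introduced copy from the endogenous gene. The annotated gene overlaps ATP7A on the same strand and PGAM4 on the opposite strand. Of the list of PGK1 copies, the testis paralog PGK2 had 0 counts in every library, and the processed copies PGK1P1 and PGK1P2 were not analysed here.

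The next comparison asked which mRNAs differed between PGK1-overexpressing and WT cells. FAM111B, a serine protease gene, went from 0.275 ± 0.101 to 37.3 ± 5.26 CPM (log2 fold change 7.07, SE 0.21, edgeR adjusted p = 1.43e-09). MCM4, a subunit of the replicative helicase, went from 14.9 ± 4.01 to 272 ± 19.9 CPM (4.19, SE 0.22, edgeR adjusted p = 5.95e-05). The other 8 of the 10 largest rises were CCNE2 (4.85), CLSPN (4.61), ZNF367 (4.58), TCF19 (4.31), ORC1 (4.23), CDC6 (4.18), TICAM2 (4.16) and MCM10 (3.85). ORC1, CDC6 and MCM10 act in loading or firing replication origins, and CCNE2 is a cyclin of S-phase entry. The TICAM2 value is uncertain, since the gene overlaps the readthrough gene TMED7-TICAM2 on the same strand and its WT level was 0.574 ± 0.899 CPM. WT replicate 3 sets that level, with 59 counts against 2 in each of WT replicates 1 and 2. Without WT replicate 3 the log2 fold change of TICAM2 was 7.48 (edgeR adjusted p = 1.51e-08). Its edgeR adjusted p of 0.0471 became 0.0890 without WT replicate 1, 0.0927 without WT replicate 2, and 0.114, 0.106 and 0.114 without PGK1_OE replicates 1, 2 and 3. It was 0.0648 without the low-count filter and 0.0975 with the replicate number as a block. CCNE2 overlaps INTS8 and NDUFAF6, and TCF19 overlaps POU5F1, each on the opposite strand.

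Among the largest falls, ASNS, the enzyme of asparagine synthesis, went from 705 ± 7.80 to 23.0 ± 2.14 CPM (log2 fold change -4.94, SE 0.06, edgeR adjusted p = 5.27e-13). The cystine transporter subunit SLC7A11 (-4.68) and the glutathione-degrading enzyme CHAC1 (-4.64) were also among the 10 largest falls. EGR1, an immediate early transcription factor, went from 50.0 ± 15.4 to 1.76 ± 0.394 CPM (-4.82). TXNIP, a thioredoxin-binding protein, went from 111 ± 27.5 to 4.64 ± 1.52 CPM (-4.58), and RND1 fell by 5.33 on the log2 scale. The fucosyltransferase gene FUT1 had 890 counts over the WT libraries and 4 over the PGK1_OE libraries, a ratio of 233 with a 95% counting interval of 90.6 to 856. SPX had 1481 and 12 counts (ratio 129, interval 73.7 to 250), and KLHDC7B had 1428 and 16 counts (ratio 93.4, interval 57.3 to 164). These exact intervals cover counting error only. BEST1 stood at 105 ± 3.07 CPM in WT and 1.03 ± 0.719 CPM in PGK1_OE (-6.63), an uncertain value because the gene overlaps the abundant FTH1 on the opposite strand. SPX overlaps GYS2 on the opposite strand.

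Of 14322 genes and assembled loci tested, 10195 (71.2%) changed, 5065 upward and 5130 downward. All levels are relative to a library's own counts, so this balance cannot show whether all mRNAs shifted together. A change of at least 2-fold was found for 3446 (24.1%), of which 1713 were higher and 1733 lower. A change of at least 8-fold was found for 309, of which 107 were higher and 202 lower. The 3 PGK1_OE values lay all above or all below the 3 WT values for 10944 of those tested (76.4%), where chance gives 10%. On the log2(FPKM + 1) scale, which understates the change of low genes, 1852 genes changed at least 2-fold.

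The series asks about ferroptosis, an iron-dependent cell death by lipid peroxidation, and names SLC7A11, so a panel of 14 ferroptosis genes was examined. Of these 14 genes 6 rose, 6 fell and 2 did not pass, and 12 passed when adjusted over the list alone. Among all entries tested 71.2% changed, so a high count is not particular to the panel. SLC7A11 (chromosome 4, 138164097 to 138242349, minus strand), the cystine-importing subunit of system xc-, stood at 237 ± 29.9 CPM in WT and 9.25 ± 3.02 CPM in PGK1_OE. Its raw counts were 9546, 7176 and 9423 in the WT libraries and 244, 481 and 336 in the PGK1_OE libraries. This is a 25.7-fold fall (log2 fold change -4.68, SE 0.28, edgeR adjusted p = 1.21e-04). Its partner subunit SLC3A2 went from 728 ± 6.34 to 103 ± 8.19 CPM (-2.82, SE 0.05, edgeR adjusted p = 9.97e-12). CHAC1 went from 24.7 ± 2.05 to 0.995 ± 0.374 CPM (-4.64, SE 0.26, edgeR adjusted p = 1.17e-06). These are mRNA levels, and protein was not measured here.

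The transferrin receptor TFRC rose from 484 ± 46.6 to 1883 ± 26.4 CPM (log2 fold change 1.96, SE 0.07, edgeR adjusted p = 9.97e-09). GCLM, the modifier subunit of the first enzyme of glutathione synthesis, rose from 22.7 ± 1.78 to 70.2 ± 8.67 CPM (1.63, SE 0.10), while the catalytic subunit GCLC fell (-0.55, SE 0.07). Smaller rises were found for GPX4, the lipid hydroperoxide reductase (0.42, SE 0.06, 53.1 ± 4.35 to 70.9 ± 2.62 CPM), and for AIFM2 (0.60, SE 0.11), LPCAT3 (0.61, SE 0.07) and FTH1 (0.48, SE 0.03). AIFM2 regenerates reduced coenzyme Q, LPCAT3 remodels phospholipids, and FTH1 is the ferritin heavy chain. PTGS2 fell by 0.95 on the log2 scale (SE 0.24, edgeR adjusted p = 0.00339). NFE2L2, which encodes the transcription factor NRF2, fell by 0.37 (SE 0.12, edgeR adjusted p = 0.0404). That call was lost without WT replicate 1, 2 or 3 (adjusted p = 0.108, 0.121 and 0.0743), without PGK1_OE replicate 3 (0.0916) and without the low-count filter (0.0613). ACSL4, which overlaps KCNE5 on the same strand, was -0.10 (SE 0.05, edgeR adjusted p = 0.101), and passed without PGK1_OE replicate 2 (0.0198) and with library totals in place of TMM factors (0.0181). HMOX1 was 0.01 (SE 0.11, edgeR adjusted p = 0.948). LPCAT3, AIFM2, FTH1 and NFE2L2 overlap other genes on the opposite strand, so their values are uncertain.

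**Figure D1:**
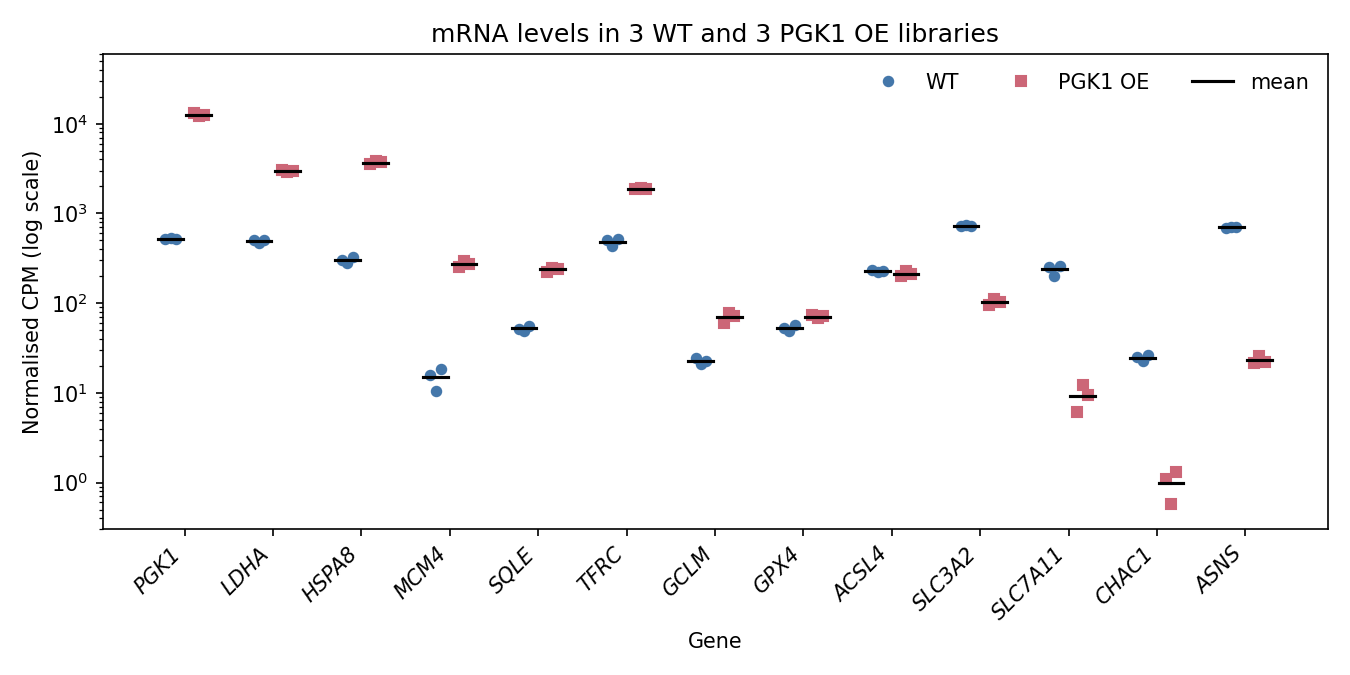
Normalised CPM on a log axis for 13 named genes, with 1 point per library (circles for WT, squares for PGK1_OE) and a black line at the mean of each group. PGK1 stood at 523 CPM in WT and 12660 CPM in PGK1_OE, and SLC7A11 at 237 and 9.25 CPM.

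Of 32 gene lists fixed before the data were examined, 30 had at least 3 tested members. With camera, which compares a list with all other genes at a preset correlation of 0.01, 17 were called, 9 upward and 8 downward. With an estimated correlation 1 list, the ATF4 targets, was called. Camera p-values were adjusted over the lists by Benjamini-Hochberg. Fry, which asks whether a list's own genes move on balance in 1 direction, called 26. Several genes are on more than 1 list, so the lists are not independent. Since 71.2% of all entries tested changed, a high count of members that passed is not in itself particular to a list. Of the members named below, WARS1, GGT7, MTHFD2, SHMT1, PRDX1, MCM7, CCNA2, H4C14, ACSL5, SLC16A3, RPE, DNAJB1, IFIT1, COL4A1 and TNC overlap another gene on the opposite strand. ALDOC, PFKFB4 and TUBB3 overlap one on the same strand, and NDUFS3 overlaps others on both. Their values may include reads of the other gene and are uncertain.

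Targets of ATF4, the transcription factor of the integrated stress response, formed the list with the smallest camera p. Of 26 tested members 25 fell and 1 rose, and 26 passed when adjusted over the list alone. The median log2 fold change was -2.37 (camera adjusted p = 1.72e-67, and adjusted p = 0.0266 with an estimated correlation). ASNS, described above, had the smallest gene-level adjusted p of the list. TRIB3, a pseudokinase, went from 702 ± 25.5 to 71.7 ± 2.73 CPM (-3.29, SE 0.05), and the aminoacyl-tRNA synthetase genes WARS1 (-2.47) and AARS1 (-2.11) fell as well. VLDLR, a lipoprotein receptor, was the member that rose (0.95, SE 0.07), and was named after its values were seen. The list of regulators of SLC7A11 turnover held 11 tested members, of which 4 rose and 6 fell, with 11 passing when adjusted over the list alone (median -0.28, camera adjusted p = 0.00901, and adjusted p = 0.197 with an estimated correlation). Among them ATF4 mRNA went from 665 ± 7.50 to 213 ± 7.94 CPM (-1.64), ATF3 from 119 ± 3.44 to 7.00 ± 0.724 CPM (-4.09), and SOCS2 fell by 2.03 on the log2 scale. Without the low-count filter this list's camera adjusted p was 0.191.

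Of 14 tested genes of cystine import and glutathione metabolism 5 rose and 9 fell, with 14 passing when adjusted over the list alone. The median was -0.56 (camera adjusted p = 0.00488, and adjusted p = 0.208 with an estimated correlation). The transsulfuration enzymes CBS (-3.36, SE 0.08, from 90.3 ± 4.75 to 8.79 ± 0.886 CPM) and CTH (-2.38, SE 0.11) fell, as did GGT7 (-0.83). Serine and one-carbon enzymes fell in 8 of 13 cases and rose in 4, with 12 passing when adjusted over the list alone (median -0.66, camera adjusted p = 0.0126, and adjusted p = 0.419 with an estimated correlation). PHGDH, the first enzyme of serine synthesis, fell by 1.85, mitochondrial MTHFD2 by 1.73 and MTHFD1L by 1.14 on the log2 scale, whereas SHMT1 rose (1.90). Without the low-count filter the camera adjusted p was 0.0646 for the cystine list and 0.0860 for the one-carbon list.

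The list of ferroptosis suppressors was not called by camera or fry (fry adjusted p = 0.461). Of 18 tested members 10 rose and 7 fell, with 17 passing when adjusted over the list alone. Its median was 0.45, while its mean was -0.08 and camera's direction was down (adjusted p = 0.935). MBOAT2, a phospholipid-remodelling enzyme, rose (1.23, SE 0.07). The list of ferroptosis drivers and markers, also called by neither (fry adjusted p = 0.369), had 18 tested members, of which 7 rose and 6 fell, with 13 passing when adjusted over the list alone. Its median was -0.04 and its mean -0.51, while camera's direction was up (adjusted p = 0.935). SAT1, a polyamine acetyltransferase, went from 113 ± 11.8 to 16.9 ± 0.561 CPM (-2.75), whereas VDAC3 (1.04) and KEAP1 (0.92) rose.

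Of 23 tested NRF2 targets 16 rose and 5 fell, with 21 passing when adjusted over the list alone (median 0.48, camera adjusted p = 0.00518, and adjusted p = 0.274 with an estimated correlation). The peroxiredoxin PRDX1 rose from 116 ± 8.98 to 448 ± 5.79 CPM (1.95), the ferritin light chain FTL by 0.87 and the quinone reductase NQO1 by 1.01 on the log2 scale. Of 16 iron-handling genes 12 rose and 2 fell, with 14 passing when adjusted over the list alone (median 0.41, camera adjusted p = 0.00216, and adjusted p = 0.200 with an estimated correlation). The iron chaperone PCBP1 (1.06) and the ferrireductase STEAP3 (1.07) rose beside TFRC.

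All 24 genes of the cell cycle list rose, and 24 passed when adjusted over the list alone. Their median was 1.92 (camera adjusted p = 2.17e-30, and adjusted p = 0.140 with an estimated correlation). PCNA, the replication clamp, rose from 26.2 ± 1.32 to 229 ± 7.08 CPM (3.13, SE 0.05), the S- and G2-phase cyclin CCNA2 from 30.0 ± 2.56 to 158 ± 5.34 CPM (2.39, SE 0.06), and MCM7 (1.90) and the mitotic checkpoint kinase BUB1 (1.45) rose too. Of 9 tested replication-dependent histone genes, whose mRNAs mostly lack polyA tails, 3 rose and 2 fell, with 5 passing when adjusted over the list alone (camera adjusted p = 0.914, fry adjusted p = 0.322). H4C14 fell by 1.86 and H2BC21 rose by 1.10 on the log2 scale.

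All 18 tested genes of cholesterol synthesis and uptake rose, and 18 passed when adjusted over the list alone. Their median was 1.97 (camera adjusted p = 2.10e-13, and adjusted p = 0.229 with an estimated correlation). SQLE, the squalene epoxidase, rose from 52.2 ± 3.35 to 238 ± 11.1 CPM (2.19, SE 0.06), and NSDHL rose by 2.09 on the log2 scale. Of 18 fatty acid and phospholipid synthesis genes 12 rose and 3 fell, with 15 passing when adjusted over the list alone (median 0.52, camera adjusted p = 0.0354, and adjusted p = 0.544 with an estimated correlation). The desaturase FADS1 (0.92) and the elongase ELOVL6 (0.88) rose, and the acyl-CoA synthetase ACSL5 fell (-1.81). FADS1 overlaps FADS2 on the opposite strand.

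Of 20 glycolytic enzymes and transporters other than PGK1, 14 rose and 5 fell, with 19 passing when adjusted over the list alone. The median was 0.98 (camera adjusted p = 4.44e-09, and adjusted p = 0.197 with an estimated correlation). Lactate dehydrogenase A, LDHA, rose from 491 ± 24.3 to 2965 ± 71.4 CPM (2.60, SE 0.04), PGAM1 from 237 ± 14.8 to 912 ± 3.43 CPM (1.95, SE 0.05), and ALDOC (1.85) and the lactate transporter SLC16A3 (1.54) rose. Of 18 hypoxia-inducible genes 16 rose and 1 fell, with 17 passing when adjusted over the list alone (median 1.04, camera adjusted p = 8.30e-12, and adjusted p = 0.111 with an estimated correlation). BNIP3 (1.94), PFKFB4 (3.03) and BHLHE40 (1.34) were among them. The pentose phosphate list was not called by camera, with 4 of 7 members rising and 3 falling, and 7 passing when adjusted over the list alone (median 0.41, camera adjusted p = 0.485, fry adjusted p = 0.0110). PGD (1.51) rose, and RPE (-0.48) and RPIA (-0.74) fell. Of 28 nuclear-encoded respiratory chain subunits 17 rose and 3 fell, with 20 passing when adjusted over the list alone (median 0.14, camera adjusted p = 0.0718, fry adjusted p = 3.18e-04). NDUFS3 (1.41) and ATP5MC3 (0.99) rose. The respiratory chain list passed without WT replicate 3 (camera adjusted p = 0.0375), without PGK1_OE replicate 1 (0.0344) and without the low-count filter (0.00828). Mitochondrially encoded genes were not analysed here.

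All 11 tested chaperone genes of the heat shock list rose, and 11 passed when adjusted over the list alone. Their median was 1.83 (camera adjusted p = 1.34e-21, and adjusted p = 0.101 with an estimated correlation). The constitutive chaperone HSPA8 rose from 304 ± 24.7 to 3696 ± 151 CPM (3.60, SE 0.06), DNAJA1 from 111 ± 2.45 to 467 ± 9.73 CPM (2.08, SE 0.04), and DNAJB1 by 1.83 on the log2 scale. HSPA1B (3.52) has a near-identical paralog, HSPA1A, so its value is uncertain. The unfolded protein response list was not called by camera. Of its 16 members 10 rose and 5 fell, with 15 passing when adjusted over the list alone (median 0.51, camera adjusted p = 0.0729, fry adjusted p = 3.40e-05). The chaperone CALR (1.83) and the secreted factor MANF (1.91) rose, while the transcription factor XBP1 (-2.10) and HERPUD1 (-0.93) fell. The list passed camera without WT replicate 2 (camera adjusted p = 0.0283), without PGK1_OE replicate 1 (0.0344) and without the low-count filter (0.0311).

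Of 16 NF-kB targets and cytokines 13 fell and 1 rose, with 14 passing when adjusted over the list alone. The median was -2.24 (camera adjusted p = 5.46e-08, and adjusted p = 0.101 with an estimated correlation). The cytokine IL24 went from 2117 ± 48.8 to 205 ± 9.90 CPM (-3.37, SE 0.04), and LIF (-2.35), RELB (-2.57) and TNFAIP3 (-2.62) fell. Of 15 immediate early genes 10 fell and 2 rose, with 12 passing when adjusted over the list alone (median -0.88, also with EGR2, which had 0 counts in PGK1_OE, at its bound of 3 counts over the group). The camera adjusted p was 6.31e-10, and adjusted p = 0.200 with an estimated correlation. MYC went from 418 ± 4.99 to 33.3 ± 1.54 CPM (-3.65, SE 0.05), and DUSP1 (-2.11) and JUN (-1.37) fell. Of 27 interferon-stimulated genes 18 rose and 3 fell, with 22 passing when adjusted over the list alone (median 0.92, camera adjusted p = 0.0734, fry adjusted p = 2.32e-04). OAS1 (2.13) and IFIT1 (3.06) rose. The interferon list passed without WT replicate 3 (camera adjusted p = 0.0499), without PGK1_OE replicate 1 (0.0494) and without the low-count filter (0.00525).

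Of 18 TGF-beta and YAP target genes 11 fell and 4 rose, with 15 passing when adjusted over the list alone (median -0.36, camera adjusted p = 0.00630, and adjusted p = 0.200 with an estimated correlation). CCN1, a matricellular protein, went from 1289 ± 55.2 to 392 ± 26.0 CPM (-1.72), and AMOTL2 (-1.69) and AXL (-0.84) fell, while ID1, a target of BMP signalling, rose (3.23). Of 25 matrix genes 15 rose and 6 fell, with 21 passing when adjusted over the list alone (median 0.55, camera adjusted p = 0.0382, and adjusted p = 0.363 with an estimated correlation). SPARC (1.09), FBN1 (0.91) and COL4A1 (0.83) rose, and TNC fell (-1.39). The list of mesenchymal and epithelial state was not called by camera or fry (fry adjusted p = 0.301), with 5 of 12 members rising and 5 falling, and 11 passing when adjusted over the list alone. Its median was 0.04 and its mean -1.01, or -0.76 with CDH1, which had 0 counts in PGK1_OE, at its bound, and camera's direction was down (adjusted p = 0.935). SNAI2 (-1.68) and ZEB2 (-1.05) fell, and the keratins KRT8 (1.05) and KRT18 (0.97), which overlap on opposite strands, rose.

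Tested markers of other cell types had group means of at most 10.4 CPM, except LCP1 and TUBB3, and none of their 5 lists was called by camera, while fry called all 5. Of 3 tested epithelial markers 2 fell, and 2 passed when adjusted over the list alone (camera adjusted p = 0.407, fry adjusted p = 3.64e-04). CDH1 had 61 counts over the WT libraries and 0 over the PGK1_OE libraries, at least 21.3-fold lower with a floor of 3 counts over the group, or at least 16.8-fold by the exact 95% interval, which includes the counting error of the WT counts. ESRP1 had 257 and 6 counts. Of 3 tested hepatocyte markers 2 fell, and 2 passed when adjusted over the list alone (camera adjusted p = 0.414, fry adjusted p = 0.00112). FGG had 225 and 0 counts, at least 78.5-fold lower with that floor, or at least 63.3-fold by the interval, and APOB had 74 and 11. Of 5 tested leukocyte markers 1 rose and 1 fell, and 2 passed when adjusted over the list alone (camera adjusted p = 0.492, fry adjusted p = 9.72e-04). LCP1, an actin-bundling protein found in many tumour lines, fell from 1603 ± 20.4 to 979 ± 35.1 CPM, and CORO1A rose from 1.56 ± 0.250 to 2.63 ± 0.477 CPM (edgeR adjusted p = 0.0197). The CORO1A call was lost without WT replicate 2 (adjusted p = 0.0639) or PGK1_OE replicate 2 (0.0796). Of 4 tested endothelial markers 2 rose, PECAM1 from 3.15 ± 0.727 to 10.4 ± 1.58 CPM and ESAM from 2.02 ± 0.0845 to 3.73 ± 0.761 CPM, and 2 passed when adjusted over the list alone (camera adjusted p = 0.851, fry adjusted p = 0.0311). Of 4 tested neural markers 2 rose, the tubulin TUBB3 from 32.3 ± 3.61 to 155 ± 7.48 CPM and SNAP25 from 3.83 ± 0.604 to 9.23 ± 1.57 CPM, and 2 passed when adjusted over the list alone. The neural list's camera adjusted p was 0.0932, and 0.0388 without WT replicate 3, and its fry adjusted p was 2.32e-04.

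**Figure D2:**
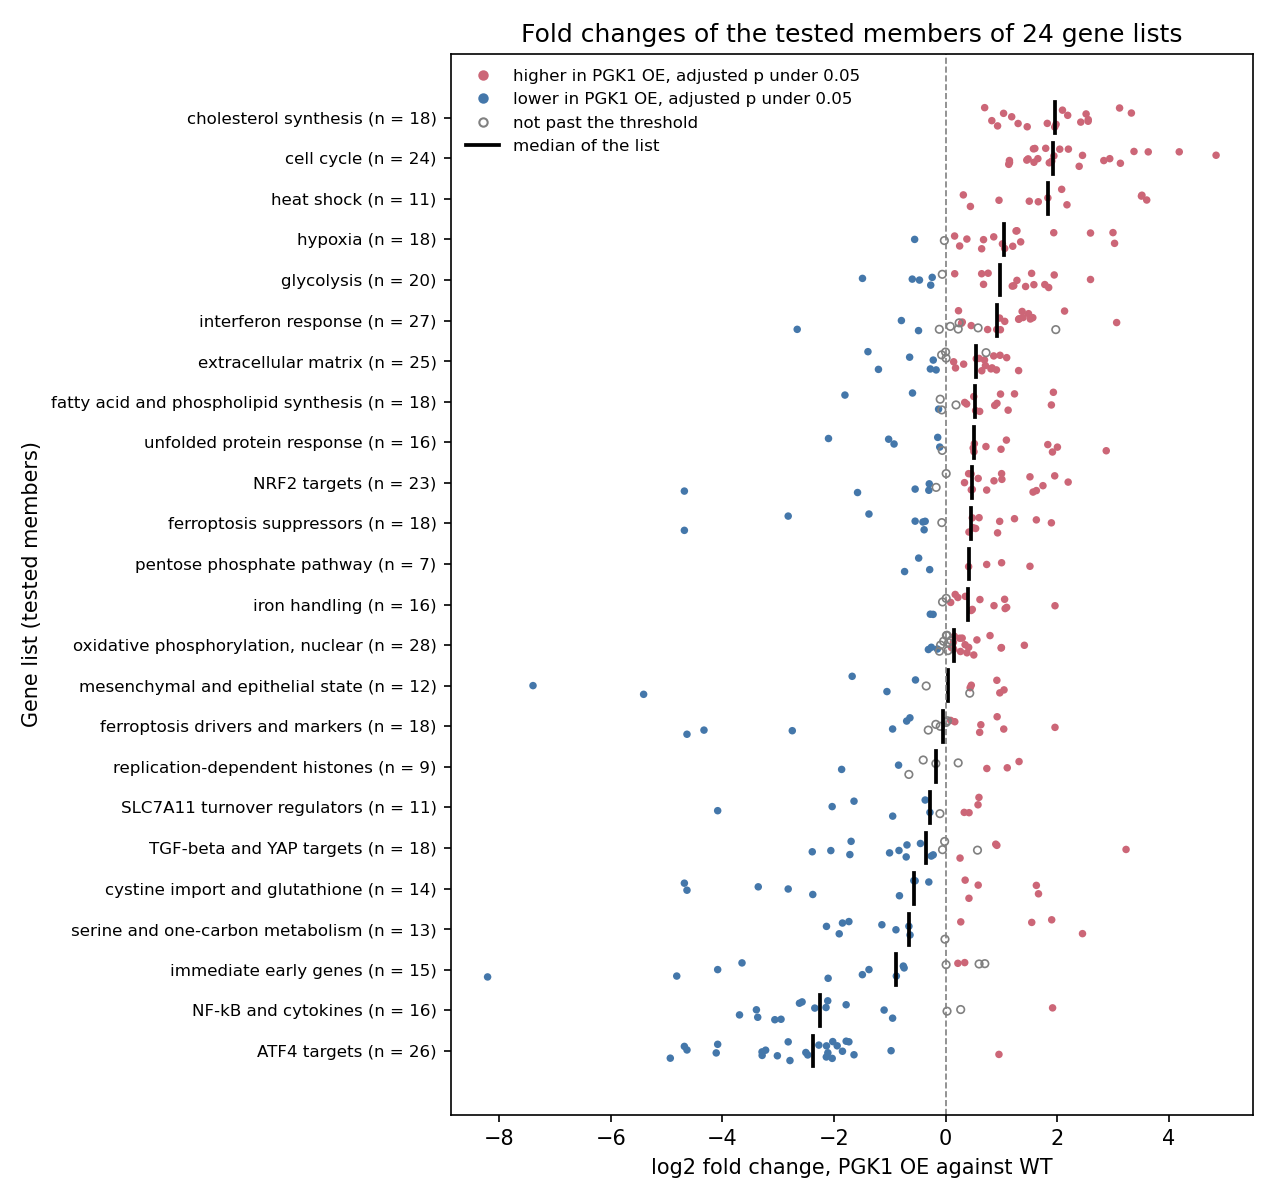
Log2 fold change, PGK1_OE against WT, of each tested member of 24 gene lists, with red dots for members that rose, blue dots for members that fell, open grey dots for members that did not pass, and a black bar at the list's median. The ATF4 targets had a median of -2.37, the cell cycle list 1.92 and the cholesterol list 1.97, and the points of CDH1 and EGR2, with 0 counts in PGK1_OE, depend on the prior count of the fit.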

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

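The MSTRG and same-symbol alternatives were chosen after seeing the data. Over all alternatives, 89 results of the comparisons counted as kept, where a count of genes or lists had to stay within 1.5-fold whatever its members. A count cannot reverse, and PGK1 expression, the comparison with a direction, kept it. Without the low-count filter the gene lists called were still 17, but 12 upward and 5 downward against 9 and 8, with 3 lists lost (SLC7A11 turnover, cystine, serine and one-carbon) and 3 gained (unfolded protein response, interferon, respiratory chain). The exceptions are 1852 genes changed at least 2-fold on the log2(FPKM + 1) scale with the FPKM filter and 1843 without it (that scale shrinks low genes), and the gene lists, of which 1 was called with an estimated correlation and 26 by fry, which tests another question. Named genes kept their side of the threshold in 2423 cases, lost it in 14 (NFE2L2, TICAM2, CORO1A) and gained it in 2 (ACSL4). Gene lists kept it in 440, lost it in 19 and gained it in 19. Where the report names a lost call, the cause was not tested. Leaving out 1 library gave 9694 to 9901 genes changed, 3348 to 3496 changed at least 2-fold, 11 to 13 panel genes, 17 to 20 gene lists and a PGK1 log2 fold change of 4.57 to 4.62. Every count of genes changed lay between 8831 (FPKM) and 10343 (limma-voom), 8924 at an adjusted p under 0.01. No scaling or unit moved the median log2 fold change of all genes by more than -0.05, and library totals moved the share of higher calls from 49.7% to 46.8%. Each scaling and unit is relative to a library's own counts, so their agreement cannot show whether all mRNAs shifted together. The labels do not state that the replicate numbers pair the libraries. Deviations of same-numbered libraries from their group means correlated at -0.01, -0.01 and 0.10. PGK1_OE replicates 1 and 2 correlated best with WT replicates 2 and 1, and PGK1_OE replicate 3 with WT replicate 3. With 3 libraries per group these values cannot settle whether the libraries are paired. With the replicate block, 9943 genes changed, 3381 at least 2-fold, with 12 panel genes, 17 gene lists and a PGK1 log2 fold change of 4.60, and of the named genes TICAM2 alone lost its call (adjusted p = 0.0975), and no gene list changed its call. Depth limits genes with few counts, such as FUT1 with 4 counts over the PGK1_OE libraries.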

Other observations

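The tests of the zinc-finger family, of the other ATF4 targets, of copy number, of culture state, of the share of counts taken by PGK1 and of splits for the 2 counts of genes changed were chosen only after the results were seen. The zinc-finger genes named ZNF, most of which encode transcriptional repressors, were on no list. Of 404 tested, 243 (60.1%) fell, 55 rose and 106 did not pass, with a median log2 fold change of -0.49, against 35.2% that fell among 13053 other genes. The median was below 0 under every scaling, unit and filter tried, from -0.26 on the log2(FPKM + 1) scale without a filter to -0.53 with library totals. On chromosome 19, where they lie in clusters, 129 of 200 fell and 18 rose, while of 773 other genes on that chromosome 210 fell and 301 rose.

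In the first pattern weighed, ATF4 targets fell and genes of the cell cycle list rose, the latter not called with an estimated correlation (adjusted p = 0.140). PGK1 held at most 1.32% of the counts, which moves the share of every other gene by -0.0173 on the log2 scale, and library totals without any composition correction moved the median of all genes by -0.05, which argues against PGK1 taking counts from other genes. Removing a smooth trend on transcript length and GC content kept 102% of the ATF4 list's median and 95.9% of the cell cycle list's median, which argues against length or GC bias. No HOX gene was switched between groups (0 of 39 at 1 CPM or more in one group and under 0.1 CPM in the other). Of the 39, 25 reached 1 CPM in a group and so could have switched, and 24 reached it in both. Among 12417 genes 45 were switched, with no other line measured as a yardstick. The HOX values argue against one group being a line with another HOX pattern. A line that shares the pattern cannot be told apart by them. A difference in culture state other than PGK1, such as density, medium or selection, cannot be told apart from an effect of PGK1, because each group is 1 set of libraries and principal component 1, with 69.2% of the variance, separates them in either case.

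The second pattern is the 25.7-fold fall of SLC7A11 mRNA. Of 18 NRF2 targets on neither the ATF4 nor the cystine list 14 rose and 2 fell, with a median of 0.61 (95% bootstrap interval 0.37 to 1.26), which argues against lower NRF2 activity as the cause. This bootstrap interval and those given below resample the genes of a set with the libraries fixed. They take the genes as independent and hold no spread between libraries or cultures. The 17 tested genes within 5 Mb of SLC7A11 had a median of -0.16 (-0.54 to 0.40), which argues against a loss of gene copies that reaches its neighbours, while a loss of SLC7A11 alone was not tested. The other 25 ATF4 targets had a median of -2.27 (-3.02 to -2.02), so lower ATF4 activity is a candidate explanation, found and tested on the same data. Whether it would follow from PGK1 or from culture state stays open, as for the first pattern.

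The third pattern is that neighbouring genes changed together. Of 1129 windows of 100 consecutive genes, the most deviating lay on chromosome 19 from 52749942 to 57727624, -0.49 from the median of all genes and beyond each of 100 shuffles (highest 0.43). ZNF genes on other chromosomes had a median of -0.33 (-0.49 to -0.24), so a fall of that family wherever it lies may account for part of this window. Of the 57 other genes in the window 22 fell and 13 rose. Their median was -0.17 (-0.52 to -0.03), against 0.07 for all genes on that chromosome not named ZNF. Whether the family's fall accounts for them too cannot be told. The split was by symbol alone, so any zinc-finger genes with other names count among them, and the window was picked as the most deviating. Without ZNF genes the most deviating window lay on chromosome 22 from 15690026 to 29057487, at 0.44 (reached by 0 of 100 shuffles) and, with the length and GC trend removed, at 0.38 (reached by 5), while an earlier draw of 100 shuffles gave 1 and 3. A copy-number difference there cannot be told apart from other causes, since it lies between the limits set for the test, and an earlier form of the test, which kept ZNF genes, was replaced after the chromosome 19 window had met it.

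With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave a result as large. The real split gave 10195 genes changed, 3446 changed at least 2-fold and 12 panel genes. The highest of the other splits gave 0 of each. Every other split mixes WT and PGK1_OE libraries, so the group difference becomes spread within its groups and hinders any call. The 0 values therefore do not measure what chance gives. By camera the real split gave 17 gene lists. The other splits gave 6 to 10 although no gene changed in them, which limits what the 17 called lists show.

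Of 780 tested MSTRG entries 386 (49.5%) changed, against 72.4% of Ensembl entries. Their median coefficient of variation within a group was 27.0%, against 6.15%.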
